A study of Mus musculus with 2 samples.

How the data were processed

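Droplet single-cell RNA was measured in cells sorted from afferent lymphatics of the submandibular nodes of FVB/N Prox1 reporter mice, as 1 library pooled from 6 adult mice (12 weeks) and 1 library pooled from 6 aged mice (93 weeks), per the labels. The cells carry no mark of the animal they came from in the tables used here, so each library counts as 1 sample. Both libraries were used.

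Per the submitters' processing notes, the tables were made with Seurat 5.0.3. The notes name the genome builds GRCm39 and mm10 without giving either a role, so no coordinates are given here. The aligner, the counting step and the filters on cells are not given in the sources used here. The deposited values are natural logs of 1 plus the UMIs of a gene scaled to 10000 UMIs per cell, as found from the values themselves: un-logged values summed to 10000 in every cell. Dividing by the smallest value of a cell gave whole numbers for 100% of the values within a tolerance of 0.01, so the UMIs of every cell were recovered. The cells as deposited held 1007 to 5997 genes in the adult table and 1002 to 5987 in the aged table. Their mitochondrial share was at most 10.0% and 9.97%, with medians of 2.40% and 2.24%. No further filter was applied.

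Both tables list 23521 genes. The aged table gives row numbers in place of gene names, so its genes were named by the row order of the adult table. This was checked on the cells found in both tables: 13582 of 13621 rows (99.7%) matched the adult row at the same position best over cells, and 39 matched another row better. Gene levels correlated at 0.996 over the same rows and at most at 0.0707 with the rows shifted.

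The barcodes shared by both tables were seen before any comparison of ages, and the choice to count them once, as adult, was made after seeing them. Shared cells had a median of 12434 UMIs in the adult table and 6294 in the aged table. The 331 cells of the adult table alone had a median of 3298 UMIs. All cells as deposited were kept as an alternative.

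The 14300 cells were clustered together without integration. Log-normalised values of 2000 variable genes, without mitochondrial, ribosomal protein, haemoglobin, sex-linked and immediate early genes, were reduced to 30 principal components with numpy 2.4.6. A graph of 15 neighbours (scikit-learn 1.9.0) weighted by shared neighbours was clustered by the Leiden method (igraph 0.11.9) at a resolution of 1. A cluster took the class whose markers had the highest mean log2 fold over the other clusters, if that mean was at least 1 and 3 or more markers were found in 10% of its cells. Clusters without such a class were called fibroblast-like if 3 or more fibroblast markers were found in 50% of their cells. A cluster with more markers of another class than of its own among its 10 leading genes was kept apart. Lymphatic endothelial-like cells were clustered again at a resolution of 0.5. The markers, the gene lists, the thresholds for genes, the rule for named genes and the comparisons were fixed before the data were examined, and the thresholds of the naming rule were not. Classes were rebuilt from the data and need not match those of the authors. Shares of cells carry exact Clopper-Pearson intervals.

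Within a class the UMIs of a gene were summed per library and divided by the class total to give counts-per-million values of the class (CPM). The log2 ratio of aged over adult CPM was taken after adding 1 CPM to each. Its 95% interval is the exact conditional binomial interval of the ratio of 2 Poisson sums, without the added CPM, so a ratio of a low gene such as Cpz can lie outside its interval. The added CPM makes ratios of low genes smaller. The intervals cover counting error only, not differences between cells, mice or libraries. Genes were measured where 10% or more of the class's cells had a UMI in at least 1 library and both libraries together held 50 or more UMIs. A class was compared where each library held 50 or more of its cells. A gene at 0 in a library is given as a bound against a floor of 3 counts of the class total of that library. Dcpp1, Dcpp2 and Dcpp3 were given no fold, since the copies of adult cells hold UMIs of them, but stay in the counts of higher genes in the classes where they were measured.

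For each fixed list the median log2 ratio of the members with 50 or more UMIs was set among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries. Lists below the 2.5 or above the 97.5 percentile were taken as standing apart. The interval of a median comes from 500 draws of the counts. Members were counted as higher or lower from 1.5-fold. The smooth muscle-like, fibroblast-like and blood endothelial-like classes were compared in the same way as the lymphatic one.

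The genes named in a class were the 12 with the highest and the 12 with the lowest log2 ratio in lymphatic endothelial-like cells, and 8 and 8 in each other class. One gene ranked this way in lymphatic endothelial-like cells is not reported here. Predicted and unnamed genes, mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, and sex-linked genes were left out of the ranking. A gene over 5 times more abundant in another class of the same library was named apart, as possible free RNA or doublets. Members of the fixed lists could be named as such, and Nos3, Prox1 and Ccl21a were named in lymphatic endothelial-like cells whatever their ratio. Genes named in the closing paragraphs on genes shared between classes and on imprinted genes were chosen after their values were seen.

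For shares of cells with a UMI at equal depth, every cell, fibroblast-like ones included, was thinned to 4081 UMIs, the 20th percentile of the lymphatic endothelial-like cells, and shallower cells were left out. For the alternative at equal depth every class was thinned to its own 20th percentile. Cells were called female or male from Xist against Y-linked genes, with at least 2 UMIs of one and 4 times those of the other. Scrublet, as in scanpy 1.11.5, called 0 adult and 1 aged doublet (0.0143%), too few to have worked, so no doublets were removed. As an added alternative, the 424 adult and 392 aged cells with the highest scores were left out, at expected rates of 5.8% and 5.6%.

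The comparison step was tested on simulated Poisson sums with 200 changed genes. The intervals assume the same model, so their coverage checks the calculation only, not the spread between cells, mice or libraries. The 95% intervals covered the true ratio for 95.9% of genes in the lymphatic endothelial-like comparison (6037 genes), 95.9% in smooth muscle-like (7696), 95.1% in fibroblast-like (8655) and 95.5% in blood endothelial-like cells (7228). Of genes changed 3-fold, 96%, 94%, 100% and 98% lay past 2-fold in these comparisons. Of unchanged genes, 0.687%, 0.187%, 0% and 0.0143% did.

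Alternatives varied the fold, the added CPM, the detection minimum, the total, the centring of the ratios, the cells taken as lymphatic, the weighting of clusters and cells, the depth, quality filters and the clustering. Another 8 alternatives were added after seeing the data. They concern shared barcodes, doublet scores, sex, equal weights of clusters, the cluster kept apart and salivary-like cells. Calculations used Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.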

Results

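Single cells of the afferent lymphatic vessels of the submandibular lymph nodes were profiled in FVB/N mice that carry green fluorescent protein under the Prox1 promoter, a reporter of lymphatic endothelium. Cells were sorted by flow cytometry before droplet capture. The design held 1 pooled library per age. The adult library came from 6 mice aged 12 weeks and the aged library from 6 mice aged 93 weeks. The adult table held 7308 cells and 90875406 UMIs (unique molecular identifiers), with a median of 12087.5 UMIs per cell and a range of 1725 to 37655. The aged table held 13969 cells and 128940414 UMIs, with a median of 8190 per cell and a range of 1433 to 50077.

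The aged table held cells under 6977 of the 7308 adult barcodes (95.5%), and these cells had a median of 0.506 times the UMIs that they had in the adult table. They were counted once, as adult. The comparison of ages therefore set the 7308 cells of the adult table against the 6992 cells found in the aged table alone, whose median was 11664 UMIs. With 1 library per age the differences have no replicate check, and no test between ages was made. All values describe these 2 libraries, and their 95% intervals cover counting error only.

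The cells fell into 24 clusters, and lymphatic endothelial-like, smooth muscle-like, fibroblast-like and blood endothelial-like classes were named from fixed markers. Lymphatic endothelial-like cells were 276 of the adult cells (3.78%, exact interval 3.35 to 4.24%) and 92 of the aged cells (1.32%, 1.06 to 1.61%). Smooth muscle-like cells were 4.35% (3.90 to 4.85%) of the adult library and 3.46% (3.05 to 3.92%) of the aged one. Blood endothelial-like cells were 8.55% (7.92 to 9.22%) and 5.98% (5.43 to 6.56%), and fibroblast-like cells 76.8% (75.8 to 77.7%) and 80.5% (79.6 to 81.5%). A fibroblast-like cluster led by Plcxd3, Cxcl13 and C7 was kept apart, with 6.54% and 8.70% of the cells. No pericyte or immune class had a cluster of its own at this resolution. At a resolution of 2 a pericyte-like cluster of 63 adult and 38 aged cells was found. The sort and the dissection can set all of these shares. The cells called female were 58.8% of the adult cells with a call and 44.8% of the aged ones.

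The first comparison asked how lymphatic endothelial-like cells of the aged library differed from those of the adult library. Of 6037 genes measured, 97 were 2-fold or more higher and 187 were 2-fold or more lower in the aged library. The sums behind them were 1721825 adult and 517336 aged UMIs, with medians of 5983 and 5453 UMIs per cell. Most cells of both libraries lay in the cluster led by Spp1, Prox1 and Nts (176 adult, 74 aged), and the rest in the cluster led by Ccl21a, Mmrn1 and Lyve1 (100 adult, 18 aged).

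Among the genes ranked highest in the aged lymphatic endothelial-like cells was Neo1, the receptor neogenin, at 55.8 CPM in the adult and 346 CPM in the aged library, a log2 ratio of 2.61 (2.27 to 3.01). Vegfc, a growth factor for lymphatic vessels, had a log2 ratio of 2.17 (1.59 to 2.88), and the heparin-binding factor Ptn had 1.55 (1.34 to 1.77). Nrgn reached 2.60, Agr2 2.02, Flrt3 1.67, Met (the receptor of hepatocyte growth factor) 1.66, Sulf1 1.63, L3mbtl3 1.62, Rida 1.55 and the stress-induced cytokine Gdf15 1.55. Neo1, Vegfc, Agr2 and Nrgn are among the leading genes of a subcluster of 16 adult and 19 aged cells, and with subclusters weighted equally the ratio of Neo1 was -0.65. Gdf15 stood at 1.23 (0.74 to 1.73) in female cells, and the male cells held 8 UMIs of it, too few for a ratio. Rida stood at 0.43 (-0.65 to 1.43) in female and 2.76 (2.01 to 3.6) in male cells. In male cells Agr2 stood at 0.69 (-0.98 to 2.20) and Sulf1 at 0.81 (-0.22 to 1.79), and in female cells L3mbtl3 stood at 0.94 (-0.30 to 2.15). Slit3 (2.13), Fabp4 (2.06) and Gsn (1.61) were also higher, but over 5 times more abundant in another class of the same library, and Gsn stood at 0.04 (-0.65 to 0.69) in male cells.

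Genes of antigen presentation were among the lowest ranked in the same class. The class II genes Cd74 (log2 ratio -5.84, 477 adult against 2 aged UMIs), H2-Ab1 (-4.85, 240 against 2), H2-Eb1 (-3.67, 189 against 4), H2-Ea (-3.35, 219 against 6) and H2-Aa (-3.10, 156 against 5) were lower in the aged library. So was the class I gene H2-Q7 (-2.72, -3.65 to -2.0), whose reads may be split with near-identical family members. The interferon-inducible GTPase Iigp1 had 850 adult and 34 aged UMIs (-2.89, -3.45 to -2.42). Myoz3 (-3.44), Trim69 (-2.71), the acute-phase gene Serpina3n (-2.66), Gstp1 (-2.40) and Mgat4a (-2.21) completed the list. Mgat4a stood at 0.07 when all cells with a Prox1 UMI and none of Ptprc, Pdgfra or Acta2 were taken instead. Of these 605 adult and 384 aged cells only 256 and 90 belonged to the lymphatic endothelial-like class. Gucy1a2 had 68 adult and 0 aged UMIs, at least 6.81-fold lower. Gucy1a2, Nexn (-2.75), Gadd45g (-2.60) and Il33 (-2.35) were over 5 times more abundant in another class. In female cells Mgat4a stood at -0.66 (-2.68 to 0.85) and Il33 at -0.83 (-2.84 to 0.66). In male cells Serpina3n and Gstp1 each stood at -1.855 (-7.390 to 0.729).

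**Figure D1:**
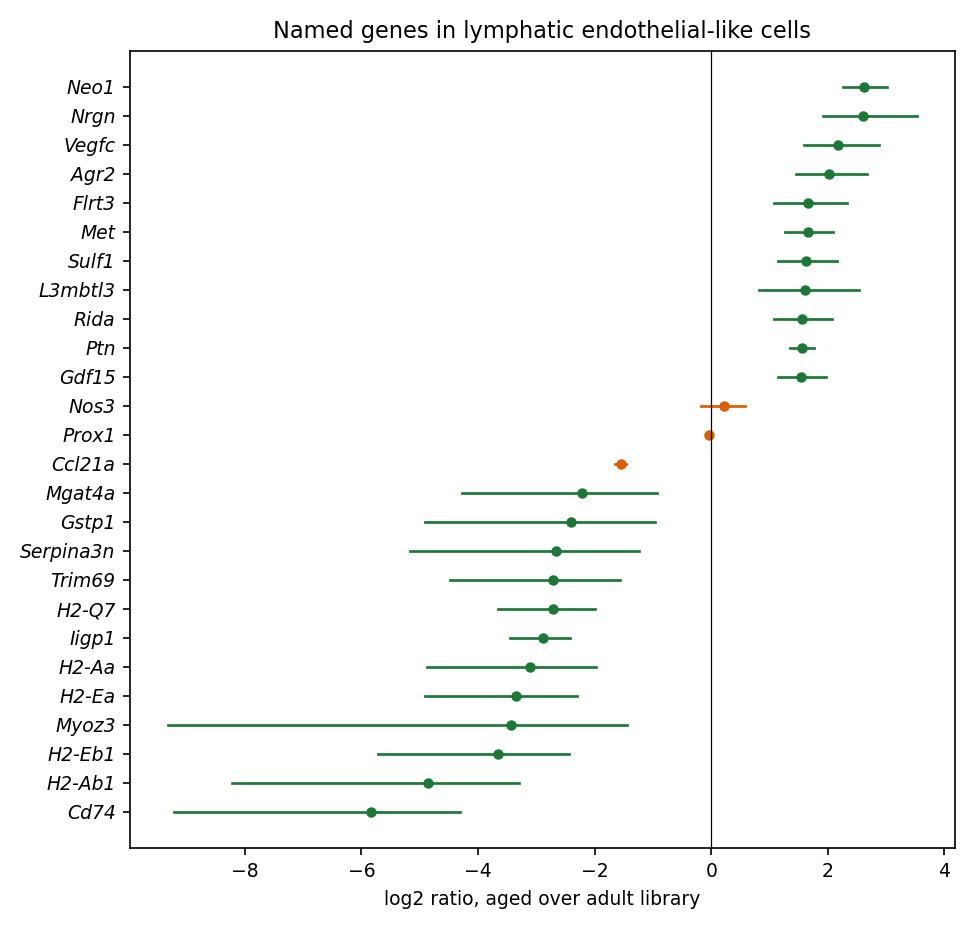
Log2 ratio of aged over adult CPM (x axis) in lymphatic endothelial-like cells for the genes named as highest and lowest and, in orange, for Nos3, Prox1 and Ccl21a; bars are 95% counting intervals. Cd74 lies lowest at -5.84 and Neo1 highest at 2.61, while Prox1 lies at -0.04 and Nos3 at 0.22.

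Nos3, the endothelial nitric oxide synthase, was named in advance because nitric oxide sets the tone of collecting lymphatics. Its log2 ratio in lymphatic endothelial-like cells was 0.22 (-0.17 to 0.59), so no difference was detectable at this depth. With every cell thinned to 4081 UMIs, 30.7% (24.7 to 37.1%) of adult and 39.1% (27.6 to 51.6%) of aged cells had a Nos3 UMI. The fibroblast-like cells, which should lack it, stood at 0.424% and 0.129% at the same depth, and the unthinned shares were 39.1% and 42.4%. Thinning left out 51 adult and 23 aged cells. The nitric oxide list had a median log2 ratio of 0.25 (0.05 to 0.41), the 93.1 percentile of matched random lists, with Ddah2 at 1.15 (0.46 to 1.88) as its only member past 1.5-fold. Prox1 itself stood at -0.04 (-0.07 to 0.00) over the class, at -0.29 (-0.35 to -0.23) in female and -0.10 (-0.17 to -0.03) in male cells, and lower in each of the 2 lymphatic clusters (last paragraph).

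Ccl21a, the chemokine that draws dendritic cells into lymphatics, had a log2 ratio of -1.55 (-1.65 to -1.46). At equal depth 34.2% (28.0 to 40.8%) of adult and 18.8% (10.4 to 30.1%) of aged cells had a Ccl21a UMI. The unthinned shares were 38.0% and 26.1%, and the thinned fibroblast-like cells stood at 0.498% and 0.129%. The lymphatic identity and growth list had a median of -0.39 (-0.54 to -0.16), the 0.01 percentile, with Sox18 at -1.39, Reln at -0.85, Nr2f2 at -0.78, Lyve1 at -0.68 and Mmrn1 at -0.61. The list stood at -0.60 (-0.88 to -0.37) in female and -0.23 (-0.47 to -0.06) in male cells. Lyve1 stood at -1.64 in female but 0.11 (-0.29 to 0.49) in male cells, and Reln at -1.49 but -0.06 (-0.48 to 0.35). Both are leading genes of the cluster led by Ccl21a, which held 51 female and 21 male adult cells but 4 and 4 aged ones. These values by sex thus rest on few aged cells, which the counting intervals do not cover. With subclusters weighted equally both signs were reversed, to 1.33 for Ccl21a and 0.25 for the list median. Such means give full weight to subclusters of as few as 10 aged cells, where a gene can lie near 0 UMIs. In both lymphatic clusters Ccl21a was lower in the aged library, at 16551 against 12277 and 121 against 51.9 CPM, as was Prox1. Reln (2080 against 2149 and 45.9 against 83.5 CPM) and Mmrn1 (3566 against 3573 and 398 against 470 CPM) were lower in neither, nor was Flt4. The lower class values of Reln and Mmrn1 thus came with the share of the cluster led by Ccl21a, 100 of 276 adult and 18 of 92 aged cells. Ccl21a, Lyve1 and Reln are also leading genes of the capillary-like subcluster.

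Reclustering the lymphatic endothelial-like cells gave 5 subclusters. The capillary-like one held 36.2% (30.6 to 42.2%) of adult and 22.8% (14.7 to 32.8%) of aged cells, and the valve-like one held 26.1% and 25%. The 10 leading genes of the valve-like one, with Spp1 and Coch first, held no fixed valve marker, so its name is weak. The other 3 subclusters stayed unnamed. One of these, led by Tmem108, Neo1, Agr2 and Vegfc, held 16 adult and 19 aged cells, and another, with Vwf and Cd74 among its leading genes, held 32 adult and 10 aged cells. The median of the class I list lay between -1.0 and -1.12 in every subcluster.

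Lists of antigen presentation, interferon response and immediate early genes were among those that stood apart in the lymphatic endothelial-like cells. The class I list had a median log2 ratio of -0.97 (-1.16 to -0.87), and none of 10000 matched random lists lay lower. Its members B2m (-1.18), H2-K1 (-1.02) and the immunoproteasome genes Psmb8 (-1.14) and Psmb9 (-1.26) were lower, with Psmb8 at -0.20 (-0.98 to 0.52) in male cells. The class II list had a median of -4.26 (-5.56 to -3.52) over 4 measured genes, all lower. At equal depth 18.7% of adult and 1.45% of aged cells had a Cd74 UMI, against 0.554% and 0.0184% of fibroblast-like cells; unthinned the shares were 17.8% and 1.09%. The interferon response list stood at -0.44 (-0.82 to -0.19), the 0.24 percentile, with Irgm1 at -1.73 and Bst2 at -1.38. With subclusters weighted equally its median was -1.158 over 10 members, but -0.178 (-1.027 to 0.036) over the 5 with a UMI in each. Immediate early genes, which dissociation can induce, had a median of -0.78 (-0.88 to -0.72) with 11 of 13 lower, among them Egr1 (-1.58) and Fos (-1.35). The extracellular matrix list was higher, at 0.40 (0.11 to 0.54) and the 99.9 percentile, with Sparc at 1.37 and Fn1 at 1.14. Its median was -0.004 in female cells alone, and Sparc stood at 0.47 (-0.49 to 1.38) in male cells. Sparc and Fn1 were over 5 times more abundant in fibroblast-like cells, where the list was higher too, so free RNA or doublets of these cells may add to its rise. The lipid handling list stood at 0.49 (-0.05 to 0.90), but at -0.11 in the cells chosen by Prox1, most of which lay outside the class.

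The lists of mechanosensing and valve genes did not stand apart from random lists in the lymphatic endothelial-like cells. The flow and stretch sensing list had a median of 0.05 (-0.17 to 0.11), the 54.5 percentile. Its members Piezo1 (0.19), Piezo2 (-0.21) and Klf2 (-0.38, but -0.84 in female and 0.23 in male cells) stayed within 1.5-fold, Trpv4 stood at 0.83 (-0.06 to 1.73) Yap1 at -0.78, with -0.39 (-1.17 to 0.31) in female cells, and Gja4, also a valve gene, at -0.68 (-1.48 to 0.03). The valve list had a median of 0.23 (0.03 to 0.39), the 89.6 percentile, and stood at 0.42 (0.11 to 0.81) in female and 0.73 (0.38 to 1.11) in male cells, with Cldn11 at 1.17 (0.79 to 1.56) and Fn1 and Neo1 higher, and Gja4 and Foxc2 (-0.59, -1.51 to 0.21) lower. Neo1 was lower with subclusters weighted equally. In the chemokine and adhesion list (-0.03) Ackr4 (1.47) and Ackr3 (0.79) were higher, and Icam1 (-1.45) and Csf1 (-1.19) lower with Ccl21a. The axon guidance gene Sema3a was higher at 1.28 (1.07 to 1.5). No other list measured in this class lay outside the central 95% of random lists.

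The next comparison asked the same of smooth muscle-like cells, since a muscle coat drives lymph along collecting vessels. Whether these cells came from lymphatic or blood vessels was not tested. In smooth muscle-like cells (318 adult, 242 aged) 48 of 7696 genes were 2-fold or more higher and 237 were 2-fold or more lower in the aged library. The sums were 2517768 and 1598551 UMIs. The higher genes were Nrep (1.87), Dmp1 (1.83), Ccrl2 (1.72), the cyclin Ccnd1 (1.66), Rergl (1.42), Pex5l (1.36), Hrc (1.34), a calcium-binding protein of the sarcoplasmic reticulum, and Fjx1 (1.31). Ccrl2 stood at -0.63 when clusters were weighted equally. In female cells Ccnd1 stood at 0.92 (-0.02 to 1.93), Hrc at 0.72 (-0.39 to 1.92) and Fjx1 at 0.81 (-0.28 to 2.0). Pex5l stood at 1.115 (-0.147 to 2.597) in female and 1.328 (-0.028 to 3.017) in male cells. The lower genes included the chemokine Cxcl10 (-5.08, -6.28 to -4.42, 667 adult against 11 aged UMIs), the interferon-inducible Gbp5 (-3.98) and Iigp1 (-3.06) and the chemokine Ccl19 (-3.41). Hpse2 (-3.43), Or2v1 (-3.40), Rasgrf1 (-3.36) and Ccn3 (-3.28) were lower too.

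In smooth muscle-like cells the contractile list had a median of 0.16 (0.11 to 0.21), the 90.3 percentile, and stood at -0.002 (-0.05 to 0.05) in female and 0.30 (0.19 to 0.39) in male cells, with Acta2 at 0.32 and Myh11 at 0.29. Actg2 (-1.08, -1.28 to -0.89) and Cnn1 (-0.91, -1.12 to -0.71) were lower. Actg2 leads a cluster that held 138 adult and 64 aged cells. The list of lymphatic pacemaking channels stood lower, at -0.22 (-0.27 to -0.06), the 1.73 percentile, with -0.11 (-0.30 to 0.01) in female and -0.17 (-0.32 to -0.03) in male cells. The ryanodine receptor Ryr3 (-1.74), the potassium channels Kcnj8 (-1.09, -1.37 to -0.83) and Kcnma1 (-0.64) were lower, and the calcium channel Cacna1h (0.72) was higher, at 1.44 in female but -0.52 (-1.56 to 0.41) in male cells. Kcnj8 was also a fixed pericyte marker, so pericytes within the class may set its level. The chloride channel Ano1 and the calcium channel Cacna1c, both needed for lymphatic pacemaking, stood at -0.26 and -0.22. The alpha-1A adrenergic receptor Adra1a was higher at 1.69 (1.12 to 2.46), with 2.80 in male and 0.55 (-0.51 to 1.65) in female cells, and the muscarinic receptor Chrm3, over 5 times more abundant in lymphatic endothelial-like cells, lower at -1.71.

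Inflammatory lists were lower in the aged smooth muscle-like cells. Medians were -1.11 (-1.26 to -0.86) for class I presentation, -0.92 (-1.16 to -0.70) for the interferon response, -0.73 (-0.87 to -0.52) for chemokines and adhesion, -0.64 (-0.72 to -0.46) for NF-kB targets and -0.62 (-0.73 to -0.46) for complement and acute phase genes. No random list lay lower than any of them. The complement list stood at -0.13 (-0.43 to 0.17) in female and -1.48 (-1.67 to -1.25) in male cells. Members included Ifit1 (-2.10), Vcam1 (-1.81), Irf7 (-1.44, with -0.48 in female cells), Cp (-1.26), B2m (-1.26) and Irf1 (-1.17). Vcam1 and Cp were over 5 times more abundant in another class. Immediate early genes stood at -0.36 and flow and stretch genes at -0.31 (with Ccn1 at -1.25 and Gja1 at -1.08, but at -0.22 in female cells), the latter list at -0.29 (-0.46 to -0.03) in female and -0.23 (-0.49 to 0.04) in male cells. The neural guidance list stood at -0.35, but at -0.08 (-0.50 to 0.25) in female and -0.29 (-0.54 to 0.08) in male cells. The oxidative phosphorylation list was higher at 0.26 (0.20 to 0.36), the 99.8 percentile, with no member past 1.5-fold. The lymphatic identity list stood at -0.88, led by Prox1 at -4.18, a transcript of another class.

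Fibroblast-like cells were compared on 73834176 adult and 69652815 aged UMIs. Of 8655 genes, 46 were 2-fold or more higher and 79 were 2-fold or more lower in the aged library. Matrix genes were among the higher ones. The matrix protein gene Postn had a log2 ratio of 1.88 (1.86 to 1.93), and the extracellular matrix list a median of 0.28 (0.26 to 0.31), with no random list higher. Its members Sparc (1.52), Col1a1 (1.3), Col3a1 (1.28) and Col1a2 (1.0) were higher and none was lower by 1.5-fold. Rian (2.22), Cpz (2.22), Cgref1 (1.95) and Igf2bp2 (1.83) were also higher. The salivary secretory genes Dcpp1, Dcpp2 and Dcpp3 had 0 adult and 164180, 111974 and 35267 aged UMIs. Over the whole aged library, 97.6% of the UMIs of Dcpp1 came from 12 cells. The copies of adult cells in the aged table held 109 UMIs of Dcpp1, so the adult counts of 0 bound no fold and none is given, although the 46 genes include them. Near-identical family members may share reads.

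The lower genes of the fibroblast-like cells were Ctla2a (-2.67), Hpse2 (-2.58), the class I transactivator Nlrc5 (-2.57), the clock gene Nr1d1 (-2.55), Trim69 (-2.30), Patl2 (-2.21), Neto1 (-1.87) and 9930111J21Rik2 (-1.87). H2-Ab1 (-3.04) was also lower, but over 5 times more abundant in another class. Class I presentation had a median of -0.86 (-0.88 to -0.84), class II of -1.96 (-2.08 to -1.77) and the interferon response of -0.51 (-0.60 to -0.42), each below all random lists. The NF-kB list was higher at 0.28 (0.27 to 0.29), with Cxcl2 (0.93), Cxcl1 (0.85) and Ccl2 (0.83) higher and Cxcl10 (-0.81) lower. The complement list stood at -0.27 (C4b at -1.09), nitric oxide signalling at -0.28 and flow and stretch genes at -0.19. Lymphatic identity genes stood at -0.318 (0.09 percentile), neural guidance genes at -0.246 (1.04) and immediate early genes at -0.155 (0.8). Sema3a (1.60), over 5 times more abundant in lymphatic endothelial-like cells, was higher and Slit2 (-1.13) lower. Lipid handling stood at 0.15, but at -0.11 as a mean over cells. The contractile list stood at -0.29, but at 0.07 with clusters weighted equally. Some fibroblast-like clusters came mostly from 1 library, such as 1213 aged against 43 adult cells in the largest one, so such a cluster may be that library rather than a type. Rian is a leading gene of that cluster, and Postn of one with 143 aged and 11 adult cells. Among the lower genes, Ctla2a and Neto1 lead a cluster of 1027 adult and 121 aged cells, Hpse2 one of 632 and 289, and Trim69 one of 810 and 307. The ratios of these genes thus partly follow cluster make-up, although no named fibroblast gene reversed under any alternative. Of the fibroblast-like cells with a sex call, 60.9% of adult and 44.7% of aged cells were female.

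Blood endothelial-like cells (625 adult, 418 aged) had 57 of 7228 genes 2-fold or more higher and 113 lower in the aged library. Zbtb16 (2.12), Pthlh (1.98), Flrt3 (1.89), the complement inhibitor Cd55 (1.60), Taco1 (1.5), Pglyrp1 (1.49), Alcam (1.46) and Cyp1b1 (1.45) were higher. So were Lhfp (2.37) and the collagen gene Col3a1 (1.54), both over 5 times more abundant in another class. The class II genes H2-Ea (-5.69, 429 against 2 UMIs), Cd74 (-4.81), H2-Aa (-4.18), H2-Eb1 (-3.73) and H2-Ab1 (-3.32) were lower, with H2-Q6 (-2.77), the coagulation factor F5 (-2.39) and Ntng2 (-2.37). F5 stood at -4.26 (-5.64 to -3.42) in female and -0.38 (-0.84 to 0.07) in male cells. Class I presentation had a median of -1.21 (-1.30 to -1.05), class II of -3.52 (-4.07 to -3.20) and immediate early genes of -0.79 (-0.84 to -0.73). The interferon list stood at -0.47 (-0.67 to -0.32), but at 0.08 in male cells, and Ifit1 (0.83) and Ifi27l2a (0.96, but -0.16 in female cells) were higher in it, the latter over 5 times more abundant in fibroblast-like cells. Chemokines and adhesion stood at 0.41 (0.10 to 0.44), with Ackr3 at 1.08 and Ccl2, over 5 times more abundant in fibroblast-like cells, at 0.75, but at -0.03 in female and 0.12 (-0.12 to 0.34) in male cells. Nos3 stood at 0.65 (0.53 to 0.77) over the class. It was higher in cluster 10 (271 against 447 CPM) but not in clusters 15 (80.8 against 78.0 CPM) and 22 (546 against 509 CPM). Ddah1 stood at 0.97. Among flow and stretch genes Trpv4 (1.18) and Ccn2 (1.16) were higher, and Klf2 (-0.63), Kdr (-0.68) and Piezo2 (-0.79) lower. Lipid handling stood at -0.24, with Gpihbp1 at -1.06, Cd36 at -0.81 and Angptl4 at 1.72.

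**Figure D2:**
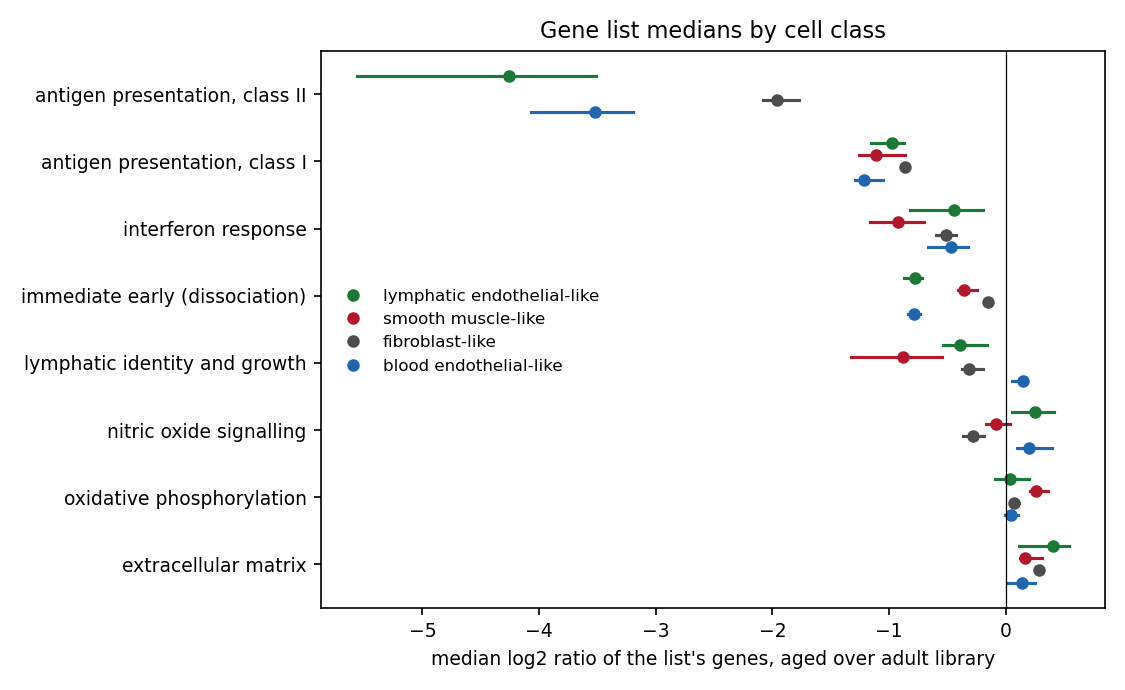
Median log2 ratio of aged over adult CPM for 8 gene lists (rows) in the 4 classes (colours); bars are 95% counting intervals. Class I presentation lies between -0.86 and -1.21 in every class, and the extracellular matrix list between 0.14 and 0.40.

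The last question was how far Prox1, the gene behind the reporter, was restricted to lymphatic endothelium. The lymphatic cluster led by Spp1 had 17854 CPM of Prox1 in the adult and 15681 CPM in the aged library, and the cluster led by Ccl21a had 7268 and 5104 CPM. Cluster 10, blood endothelial-like and led by Vwf, Selp and Emcn, had Prox1 at 2340 and 2315 CPM, with a UMI in 84.2% and 95.2% of its 366 adult and 290 aged cells. The reporter's transcript stood at 2623 and 3497 CPM there. The other blood endothelial-like clusters had 179 and 21.3 CPM (cluster 15) and 19.9 and 193 CPM (cluster 22) of Prox1.

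**Figure D3:**
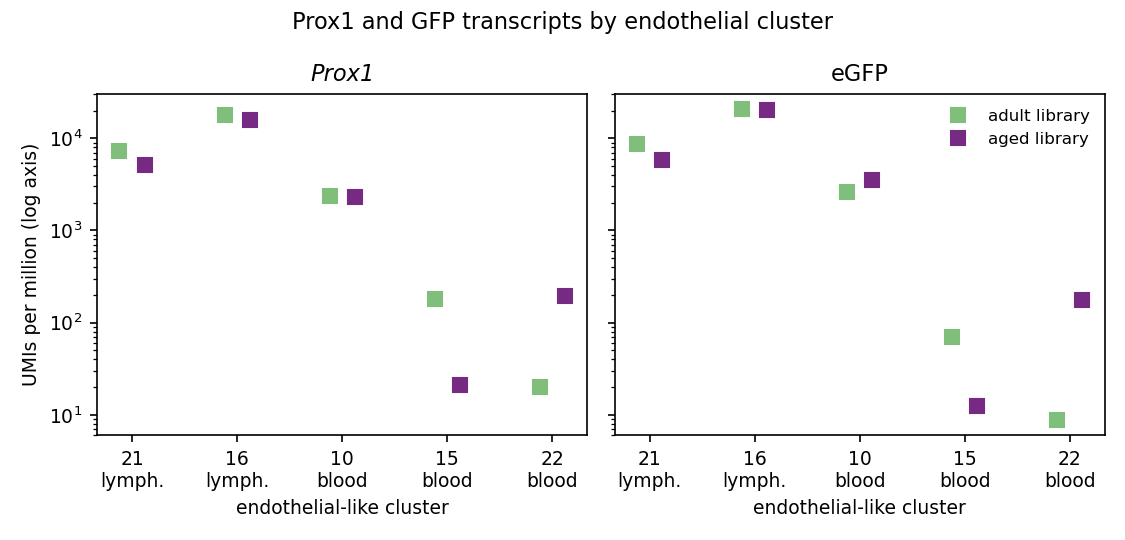
Prox1 and reporter transcript CPM (log axis) in the lymphatic and blood endothelial-like clusters of the adult and aged libraries. Cluster 10 lies at 2340 and 2315 CPM of Prox1, between the lymphatic clusters and the other blood endothelial-like clusters.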

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

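The test of whether the aged table holds the adult cells a second time was chosen only after the shared barcodes were seen.

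The aged table held cells under 6977 of the 7308 barcodes of the adult table, a signal in cells that the comparisons of age leave out. Chance collisions of barcodes between different cells are argued against by sex: all 4056 shared barcodes with a call in both tables had the same sex (100%, exact interval 99.9 to 100%), against 53.4% of shuffled pairs. Counts also differed less between tables for the same barcode, with a median chi-square per gene of 0.547, than for different barcodes, with 6.08, over 1000 cells drawn. A second copy of the adult cells at lower depth is consistent with the cells that were missing: 80.7% of the 331 adult-only cells fell below the lowest gene number of the aged table (1002) when thinned to the depth of the copies, against 0.129% of the shared cells. How such copies entered the table stays open, and no biological explanation was tested.

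Dcpp1 had 0 UMIs in the adult table but 109 in the copies of the same cells in the aged table, which are shallower, and 167828 in the cells of the aged table alone. The counts for Dcpp2 were 0, 73 and 114676, and for Dcpp3 0, 18 and 36109. A count of 0 in the adult table is thus not matched in the copies, so no fold is given for these genes, and no explanation was tested. Of the 8664 genes measured in the shared cells, 3 were 2-fold or more apart between copies and originals, all higher in the copies, and these were the pseudogenes Rpl10-ps3 (1.19), Ftl1-ps1 (1.32) and Rpl9-ps6 (1.12), named after their values were seen.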

How the results depend on the processing

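The alternatives on shared barcodes, sex, doublet scores, equal weights of clusters, the cluster kept apart and salivary-like cells were chosen only after results were seen. No paired analysis was possible because each age has 1 pooled library.

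Of 522 values of lists that stood apart, 330 stayed within their counting interval, 182 moved outside it with the same sign and 10 reversed. Of 959 values of named genes the numbers were 587, 366 and 6. Of 134 counts of genes 86 stayed within 1.5 times the main count and 48 did not, and of 44 shares 27 stayed within their interval and 17 did not. Class I presentation was lower in every class under every alternative run. Quality filters, a total without mitochondrial, ribosomal protein and immediate early genes, and centring left every count of genes within 1.5 times. The alternative with Scrublet's own calls was not run, because the caller did not work.

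Counts are given as genes higher and lower in the aged library, in the order lymphatic endothelial, smooth muscle, fibroblast and blood endothelial-like. The main counts were 97 and 187, 48 and 237, 46 and 79, and 57 and 113. At 1.5-fold they were 479 and 558, 297 and 812, 154 and 332, and 326 and 367, since a lower fold passes more genes. With 10 CPM added they were 47 and 98, 19 and 108, 25 and 33, and 33 and 48. With detection in 25% of cells they were 45 and 61, 20 and 34, 26 and 25, and 31 and 27, over fewer genes. With detection in 5% of cells, 137 fibroblast genes were lower, and 91 blood endothelial genes were higher and 190 lower. A counting interval that left out 1.5-fold gave 53 and 74 in lymphatic endothelial-like cells and 153 lower in smooth muscle-like cells, and thinning to equal depth left 150 lower there.

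With all cells as deposited, so that copies of adult cells stood on the aged side, the counts were 2 and 7, 6 and 15, 14 and 10, and 8 and 3. The aged shares were then 2.42% lymphatic endothelial, 78.8% fibroblast and 7.19% blood endothelial-like. This follows from the construction, since copies dilute any difference.

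Cells taken by a Prox1 UMI instead of clusters gave 58 higher genes, Mgat4a at 0.071 and lipid handling at -0.11. Only 256 of these 605 adult and 90 of these 384 aged cells were lymphatic endothelial-like by cluster, so the set is mostly other cells. With subclusters weighted equally, 543 genes were lower in lymphatic endothelial-like cells, Neo1 stood at -0.65, Ccl21a at 1.33 and lymphatic identity and growth at 0.25. These means include subclusters of as few as 10 aged cells, where genes at or near 0 UMIs can weigh heavily. Ccl21a stood at 16551 adult and 12277 aged CPM in the cluster it leads and at 121 and 51.9 CPM in the other. Reln and Mmrn1, members of the lymphatic identity and growth list, were lower in neither cluster. With clusters weighted equally, fibroblast-like cells had 28 higher and 46 lower genes and a contractile median of 0.074, and Ccrl2 stood at -0.63 in smooth muscle-like cells. As a mean over cells, lipid handling in fibroblast-like cells stood at -0.11. The cause was not tested.

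In female cells the extracellular matrix list of lymphatic endothelial-like cells stood at -0.004. Blood endothelial-like cells had 91 higher and 178 lower genes, and chemokines and adhesion at -0.035. In male cells 118 genes were lower in lymphatic endothelial-like cells, lipid handling stood at -0.11, and Gdf15 at -4.17 on 8 UMIs, whose interval reached 1.05, so this is no measured change. Blood endothelial-like male cells had 124 higher genes and an interferon median of 0.078. The mean of both sexes gave 377 lower genes, Gdf15 at -1.47 for the same reason, lipid handling at -0.057 in lymphatic endothelial-like cells, and haemoglobin at 0.50 in blood endothelial-like cells. The last list had stood at -6.21, or -5.79 with genes at 0 set to their bound. Fewer cells, 67 male adult and 22 male aged lymphatic ones, limit these values, and the cause of the signs was not tested.

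Shares depended on the clustering, adult then aged. At a resolution of 2 they were 2.78% and 0.987% lymphatic endothelial, 3.49% and 2.92% smooth muscle and 66.2% and 74.0% fibroblast-like. At 0.5, adult smooth muscle-like cells were 5.04% and fibroblast-like cells 82.6% and 88.9%. With each library clustered on its own, fibroblast-like cells were 70.1% and 71.7% and adult blood endothelial-like cells 7.79%. Without the highest doublet scores fibroblast-like cells were 77.8% and 82.1%.

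At the depth of lymphatic endothelial-like cells, 517336 aged UMIs, 0.687% of unchanged genes and 96% of genes changed 3-fold lay past 2-fold in simulated data, against 0% and 100% in fibroblast-like cells with 69652815. Of genes changed 2-fold, 48%, 46%, 26% and 44% did.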

Other observations

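The genes of the next 2 paragraphs, the free RNA test of Prox1, the alternatives by sex and by equal weights of clusters, and the count of transcripts far below Prox1 were chosen only after results were seen, as were the split of class I presentation from the interferon response and the use of the intervals of these medians.

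Genes different in all 4 classes were few. Of 5184 genes measured in every class, 6 were 2-fold or more lower in the aged library in all 4: B2m, Iigp1, Irgm1, Polg2, Sema4a and Trim69. Independent classes would give 4.43e-05 such genes, but the classes share the same 2 libraries. Trim69, a ubiquitin ligase, stood at -2.71 in lymphatic endothelial, -2.73 in smooth muscle, -2.30 in fibroblast and -2.31 in blood endothelial-like cells. The semaphorin gene Sema4a stood at -1.58, -1.27, -1.59 and -1.66 in the same order. Polg2, which encodes a subunit of the mitochondrial DNA polymerase, stood at -1.55, -1.05, -1.46 and -1.12. Dcpp1, at 0 adult UMIs in each class, is left out for want of a bound. No other gene was 2-fold or more higher in all 4, and Evl, Sparc and Zbtb16 were 1.5-fold or more higher. Sparc, a matrix protein over 5 times more abundant in fibroblast-like than in lymphatic endothelial-like cells, stood at 1.37, 0.83, 1.52 and 0.79, Evl, a regulator of actin, at 0.61, 1.22, 1.31 and 1.22, and the transcription factor gene Zbtb16 at 0.80, 0.78, 1.52 and 2.12.

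The imprinted genes Meg3, Rian and Peg3 were higher in the fibroblast-like cells of the aged library; other imprinted genes were not counted. The non-coding RNA Meg3 had a log2 ratio of 1.46 (1.43 to 1.49) and Rian, a neighbour in the same imprinted region, 2.22 (2.19 to 2.31). The paternally expressed Peg3 stood at 1.25 (1.20 to 1.35). In smooth muscle-like cells Meg3 stood at 0.21 (0.03 to 0.40), Rian at 0.35 (-0.03 to 0.73) and Peg3 at 1.15 (0.63 to 1.76). Whether the classes differ was not tested.

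Class I presentation was lower in the aged library in all 4 classes, with medians from -0.86 to -1.21. With an explanation removed, a list it accounts for was expected beforehand above -0.20. With every cell thinned to 1 number of UMIs no interval reached above -0.83 (smooth muscle-like). CPM are already scaled to the class total, so thinning mostly changes how cells are weighted and could not decide on depth. Tables argue against the sex make-up of the pools as the whole cause, with intervals up to -0.65 (male lymphatic endothelial-like cells). They argue likewise against the cluster make-up, with intervals up to -0.60 (smooth muscle-like) with clusters weighted equally. The copies of adult cells in the aged table differed from their originals by -0.06 to -0.01, so the table itself does not lower the list. A difference between the libraries other than age, such as batch or health of the mice, cannot be told apart from age with 1 library per age, and age stays open as an untested biological difference.

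The interferon response was lower too, with medians from -0.44 to -0.92. The bound of -0.58 first set for depth and clusters lay beyond 3 of these 4 medians before any correction, so it could not decide, and the intervals were set against -0.20 as for class I. Thinned intervals reached up to -0.22 (lymphatic endothelial-like), which again could not decide on depth. Tables argue against sex make-up as the whole cause outside blood endothelial-like cells, with intervals up to -0.23 (male fibroblast-like). They argue likewise against cluster make-up in smooth muscle and blood endothelial-like cells, with intervals up to -0.26. Sex make-up cannot be told apart in blood endothelial-like cells, with 0.078 (-0.22 to 0.26) in male cells, nor cluster make-up in fibroblast-like cells (-0.37, -0.48 to -0.17) and in lymphatic endothelial-like cells, where the median was -1.16 over 10 members but -0.18 (-1.03 to 0.036) over the 5 with a UMI in every subcluster. A difference between the libraries other than age also stays open with 1 library per age, as does age, untested.

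Prox1 and the reporter's transcript were found in blood endothelial-like cluster 10, at 2340 and 2315 CPM of Prox1 in the adult and aged library. Free RNA is argued against, since Prox1 stood there at 13.0 and 12.0 times the higher of the other blood endothelial-like clusters, against a bound of 5 times. For doublets with lymphatic cells the test set beforehand could not decide. The other transcripts abundant in lymphatic cluster 16 and rare in clusters 15 and 22 reached a median of 7.47% of their lymphatic level in the adult library (32 transcripts) and 5.78% in the aged one (27), against 12.6% and 14.2% for Prox1, and the bound set beforehand, 0.25 of the share of Prox1, was not met. Of these transcripts 14 adult and 11 aged ones lay below that bound, such as Mmrn1, at 0 in cluster 10 against 398 and 470 CPM in cluster 16, and Spp1, at 8.13 against 2585 CPM in the adult library, while 14 and 8 lay at or above Prox1. Doublets would bring the low transcripts along with Prox1, so these argue against doublets as the whole cause. Prox1 was also found in 95.2% of the 290 aged cells of cluster 10, while the aged library held 92 lymphatic endothelial-like cells. Doublets as a part of the signal cannot be told apart. Blood endothelial cells with an active Prox1 gene stay open as a biological explanation, untested.

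A few cells held most UMIs of some secreted and blood products. In the aged library 12 cells held 97.6% of the UMIs of Dcpp1, and the other cells stood at 44.1 CPM. In these 12 cells Dcpp1 made up 37.9%, Dcpp2 25.9%, Dcpp3 8.15%, Bpifa2 3.39% and Wfdc18 3.09% of the UMIs. In the adult library 4 cells held 95.7% of the UMIs of the haemoglobin gene Hbb-bs, and the median of the haemoglobin list was -4.32 in fibroblast-like cells.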
